A study of Mus musculus with 21 samples.

How the data were processed

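Total RNA from testes of 21 individual mice at postnatal day 10 had been sequenced on 1 flowcell after poly-A selection with a kit that does not keep the strand, so antisense reads are not told apart from sense reads. The deposited table holds 1 line per Ensembl gene and 1 set of columns per animal. The authors' raw read counts in it are whole numbers and were the input of every test here. The authors' normalized signal is each raw count divided by 1 size factor per library, with 100% of genes within 0.1 percent of a constant ratio in every library, and a further deposited signal is that value divided by gene length in kb. The authors also deposited log2 fold changes and, per the file headers, a p-value and an adjusted p-value for the 4 comparisons of treatment with vehicle, all rounded to 2 decimals. The submitters' processing notes name CASAVA 1.8.2, Bowtie, TopHat2 2.0.10 and Bowtie2 2.1.0 with the mm10 mouse genome. The read counter, the annotation release, the handling of reads that match several places and the authors' test are not stated there. Gene symbols, positions and types were those of the deposited table and a mouse annotation of the same build, and 36 symbols were shared by more than 1 gene. Genes with near-identical copies (globins, MHC class I genes, ribosomal protein genes, processed pseudogenes) can share reads, which makes their values uncertain.

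The total counts per library were 45459367, 40755712, 44612774 and 39958225 in WT vehicle animals T66, T71, T79 and T81, and 50171437, 41482184, 45614371 and 45461370 in WT BPA animals T60, T75, T61 and T74. They were 50307432, 47128872, 55605367 and 35459523 in WT stigmasterol animals T78, T98, T118 and T119, and 49597994, 61498855 and 38943327 in KO vehicle animals T1, T90 and T110. KO BPA animals T25, T83 and T117 had 42745033, 43675060 and 40261602, and KO stigmasterol animals T10, T15 and T93 had 43456684, 44683601 and 57987087. The 50 most abundant genes took 6.7% to 8.6% of the counts and mitochondrial genes 1.47% to 2.14%. A count of 3 corresponded to 0.049 to 0.085 counts-per-million (CPM), which serves as the floor of detection. Over 27 pairs of replicate animals the chi-square per degree of freedom of their counts was 9.9 to 82.7, so animals differed by more than counting error, and the tests use the spread between animals. Intervals given for a single library are 95% Wilson intervals and cover counting error only. The p-values treat each animal as a replicate, and litters are not given in the sources used here.

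Groups were genotype by treatment, 6 in all. Counts were fitted with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr (minimum count 10, minimum total count 15; 20254 of 32643 genes kept, 564 had no read), a quasi-likelihood model with 1 mean per group, and Benjamini-Hochberg adjustment within each contrast at 0.05. Unless another tool is named, each adjusted p of a gene is from this edgeR test, two-sided. The contrasts, the 30 gene lists, the rule for naming genes, the first set of other analyses and the groupings of libraries described here were set before the data were examined. The 8 contrasts were KO against WT in vehicle, BPA and stigmasterol against vehicle within each genotype, the interaction of each treatment with genotype, and KO against WT averaged over the treatments. Fold changes are log2 values from the edgeR fit with its default prior count. SE is the absolute log2 fold change divided by the square root of its quasi-likelihood F statistic. Levels are CPM after TMM with the SD between animals. A prior count of 2 was used only where CPM were turned to log2, as for the list tests and scores.

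The 30 gene lists were written from textbook knowledge of the postnatal testis, of FXR and sterol biology and of tissues a dissection can carry along. They were tested with camera from limma 3.58.1 (preset correlation 0.01, Benjamini-Hochberg over the lists of a contrast), with camera under an estimated correlation and with fry, which asks whether the members of a list move on balance in 1 direction, or in any direction in its mixed form. Neither form of fry compares a list with other genes. The camera adjusted p values of the lists come from 240 tests. A list of 82 cytosolic ribosomal protein genes and a liver list of 15 genes were written after the data were seen.

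In each contrast the rule for naming genes took the 10 largest rises and 10 largest falls among called genes with a conventional symbol, a mean of at least 1 CPM in the higher group and, in comparisons of 2 groups, no overlap between groups. It added called members of the lists, at most 4 per list, and the 3 members with the smallest p of each called list. In the genotype contrasts it added Nr1h4, Nr0b2, Nr0b1, Slc51a and Slc51b. Where fewer than 10 genes passed, it took the 10 smallest p, given as values. Some genes that the rule took are not reported here. The text gives the others of the first and last kinds and part of the list members. Alb, Cdh16 and the ribosomal and MHC genes set beside each other were chosen after their values were seen.

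The first set of other analyses was DESeq2 size factors, no filter, the DESeq2 1.42.0 Wald test, limma-voom with quality weights, a fit of only the groups compared, the animal number as covariate, a robust fit, and leaving out each library of a comparison in turn. Alternatives added after the data were seen were the score of the epididymis list as covariate, the score of the meiotic list as covariate, a gene length trend removed per library, leaving out the 2 WT BPA libraries with liver transcripts, leaving out the 9 libraries with Cdh16 at 10 CPM or more, and leaving out each library for the lists and for the agreement between treatments. Agreement between treatment effects was measured by Pearson and Spearman correlation across tested genes and compared with 20 simulations of unchanged groups. Other groupings of the same libraries, at most 100 per contrast, were fitted in the same way.

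The analysis was tested on simulated data with the dispersion and depth of these libraries, with 200 changed genes. In the comparison of vehicle genotypes 49.3% of 67 genes changed 1.5-fold, 80.6% of 67 changed 2-fold and 93.9% of 66 changed 4-fold were recovered, with 7 false among 156 calls. For BPA in WT the shares were 55.2%, 80.6% and 100%, with 8 false among 165 calls by edgeR, 24 among 185 by DESeq2 and 2 among 157 by limma-voom. For BPA in KO the shares were 35.8%, 74.6% and 95.5%, for the BPA interaction 16.4%, 46.3% and 71.2%, and for the averaged genotype contrast 71.6%, 92.5% and 100%. Of 30 simulated lists of 30 genes, the 1 list raised 1.2-fold was called, and 0 unchanged lists were. Genes were drawn independently in the simulations, so members of a simulated list were not correlated. The simulation therefore cannot show how camera with the preset correlation behaves on lists whose members move together.

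Left out were genes below the filter, and the authors' normalized and length-divided values, which were not used in the tests. No batch is given in the labels, and all libraries share 1 flowcell, so no batch term was fitted.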

Results

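RNA was sequenced from the testes of 21 mice at postnatal day 10, an age at which the seminiferous tubules hold Sertoli cells, spermatogonia and the first germ cells entering meiosis. The animals were wild type (WT) or knockouts (KO) of FXRα, the bile acid receptor encoded by Nr1h4, and their strain is labelled as a mix of 129sv and C57Bl6. Each genotype had a vehicle group, a group given bisphenol A (BPA), a plastics monomer with weak estrogenic activity, and a group given stigmasterol, a plant sterol. The 3 WT groups held 4 animals each and the 3 KO groups held 3 each. The doses are not given in the sources used here. The libraries held 35459523 to 61498855 counted reads, and 20254 of 32643 annotated genes had enough reads to be tested. Replicate animals varied by a biological coefficient of 19.2%. The leading principal component held 27.4% of the variance between libraries and the next held 16.8%.

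Nr1h4 (ENSMUSG00000047638, chromosome 10, 89454234 to 89533585, mm10) was detected in every library at a low level. It averaged 0.526 ± 0.18 counts-per-million (CPM; SD, n = 12) in WT testes and 0.306 ± 0.0886 CPM (SD, n = 9) in KO testes. In WT vehicle animals T66, T71, T79 and T81 its level was 0.351, 0.626, 0.536 and 0.639 CPM. In WT BPA animals T60, T75, T61 and T74 it was 0.371, 0.691, 0.868 and 0.241 CPM, and in WT stigmasterol animals T78, T98, T118 and T119 it was 0.547, 0.303, 0.582 and 0.56 CPM. KO vehicle animals T1, T90 and T110 had 0.221, 0.29 and 0.279 CPM. KO BPA animals T25, T83 and T117 had 0.343, 0.492 and 0.172 CPM, and KO stigmasterol animals T10, T15 and T93 had 0.318, 0.331 and 0.308 CPM. These values rest on 7 to 40 reads per library, so that the 95% Wilson interval of the lowest, KO BPA animal T117, was 0.0834 to 0.355 CPM and that of the highest, WT BPA animal T61, 0.638 to 1.18 CPM. The log2 fold change of Nr1h4, KO against WT, was -1.02 ± 0.403 (SE, adjusted p = 0.16) in the vehicle groups and -0.78 ± 0.229 (adjusted p = 0.0303) averaged over the treatments. The averaged call was lost without WT BPA animal T61 (adjusted p = 0.0567), KO vehicle animal T1 (0.0598), KO BPA animal T117 (0.0578), or KO stigmasterol animal T10 (0.0511) or T93 (0.0512), and its adjusted p ranged from 0.0179 to 0.516 over the other alternatives. The genotype ranges overlapped, and which part of the gene was deleted is not given in the sources used here, so a count over the whole gene does not check each animal's label. Among the genes named here Rxfp1 had the smallest p between genotypes, and it separated all animals, lying between 0.291 and 0.657 CPM in the 12 WT libraries and between 9.08 and 23.6 CPM in the 9 KO libraries.

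Some libraries carried transcripts of tissues that lie next to the testis or outside it. Cdh16, a cadherin of epididymal and kidney epithelium, reached 10 CPM or more in 9 libraries, 3 of the 12 WT and 6 of the 9 KO. It was highest in KO stigmasterol animals T93 (203 CPM) and T10 (86 CPM) and KO vehicle animal T1 (39.9 CPM). Alb, the main plasma protein of the liver, was at 578 CPM in WT BPA animal T61, 58.6 CPM in WT BPA animal T75 and 18.9 CPM in KO BPA animal T25, and at 0.15 to 7.67 CPM in the rest. Car3 and Fabp4, abundant in fat, were at 33.6 and 35.8 CPM in KO BPA animal T117. The main counts are therefore also given without such libraries, an alternative chosen after the data were seen. Leaving out the 9 Cdh16 libraries leaves 1 KO animal per treatment (T90, T25 and T15), which is assumed to vary as the WT animals do.

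**Figure D1:**
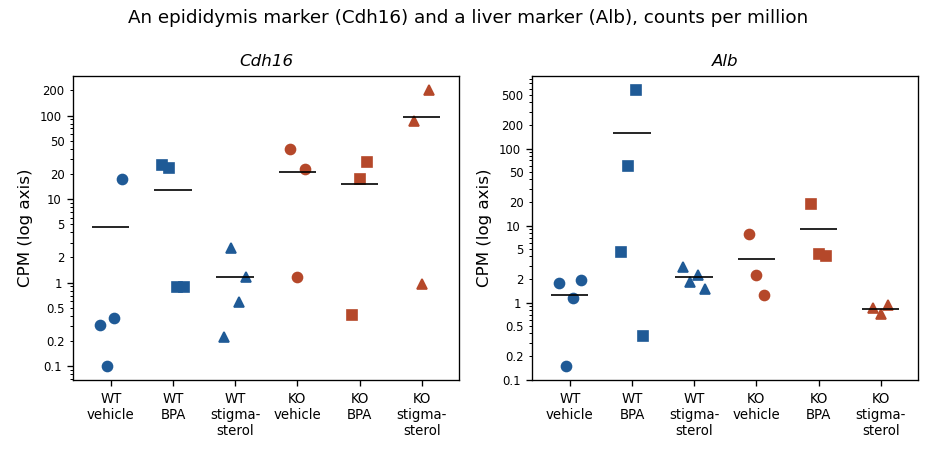
Cdh16 and Alb in CPM on log axes, 1 dot per library (blue WT, red KO; circle vehicle, square BPA, triangle stigmasterol), with a black line at each group's mean. Cdh16 reaches 203 CPM in KO stigmasterol animal T93, and Alb reaches 578 CPM in WT BPA animal T61.

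The vehicle groups ask what the loss of FXRα does in the untreated testis. Rxfp1 (ENSMUSG00000034009), a receptor for relaxin, rose in KO testes from 0.394 ± 0.129 CPM (SD, n = 4) to 13.5 ± 4.91 CPM (SD, n = 3), a log2 fold change of 5.08 ± 0.263 (SE, adjusted p = 6.94e-10). Olfml3 (ENSMUSG00000027848), a secreted matrix protein, fell from 53.8 ± 7.52 to 9.97 ± 1.69 CPM (-2.43 ± 0.286, adjusted p = 4.99e-05). H2-Q10 (ENSMUSG00000067235), an MHC class I gene, fell from 72 ± 18.9 to 1.86 ± 0.212 CPM (-5.27 ± 0.644, adjusted p = 7.71e-05), while the cytokine gene Lta (ENSMUSG00000024402) rose from 0.228 ± 0.114 to 1.41 ± 0.206 CPM (2.62 ± 0.328, adjusted p = 0.000103). In all, 592 genes passed an adjusted p of 0.05 in edgeR, 251 higher and 341 lower in KO, and 234 of them differed at least 2-fold (137 higher, 97 lower). The groups did not overlap for 3305 genes, 16.3% of those tested, where chance gives 5.7%.

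Rxfp1, Olfml3 and Tmod4 lie on chromosome 3 (79641611 to 79737880, 103733700 to 103738001, and 95124476 to 95129209), and H2-Q10 and Lta on chromosome 17 (35470089 to 35474563 and 35203165 to 35205351). The other large rises were Ccnd3-ps (log2 fold change 5.9 ± 1.17, adjusted p = 0.00852), Akt2-ps (5.67 ± 0.529, 2.3e-06), Erdr1 (5.07 ± 1.32, 0.0437), the axonemal dynein Dnah6 (3.72 ± 0.606, 0.00157), Pianp (2.98 ± 0.471, 0.00115), the tropomodulin Tmod4 (2.63 ± 0.175, 2.81e-08), Ppm1n (2.4 ± 0.228, 2.83e-06) and Igsf23 (2.33 ± 0.23, 4.84e-06). The other large falls were Eps8l1 (-3.12 ± 0.766, 0.0326), the α-globin gene Hba-a2 (-3.07 ± 0.717, 0.0255), the glucose transporter Slc2a2 (-2.89 ± 0.459, 0.00121), Rimbp2 (-2.61 ± 0.686, 0.0458), Prph2 (-2.49 ± 0.651, 0.0443), Shisa7 (-2.31 ± 0.273, 5.13e-05) and Guca1b (-2.05 ± 0.447, 0.0176). Ccnd3-ps, Akt2-ps, Erdr1, Hba-a2 and H2-Q10 have near-identical copies, so the gene their reads came from is uncertain. Hba-a1, the copy of Hba-a2, was at 13.3, 2.93, 7.06 and 10 CPM in WT vehicle animals T66, T71, T79 and T81. In KO vehicle animals T1, T90 and T110 it was at 8.92, 11.4 and 42.4 CPM. The fall of Hba-a2 is therefore not shown to be a fall of α-globin transcripts as a whole. With 1 of the 7 libraries left out in turn, Erdr1 was called 0 times (highest adjusted p 0.13), Eps8l1 and Prph2 1 time each (0.13 and 0.121), Rimbp2 2 times (0.156), Hba-a2 3 times (0.114) and Guca1b 5 times (0.0878). The remaining genes of these 19 kept their call in all 7 fits.

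**Figure D2:**
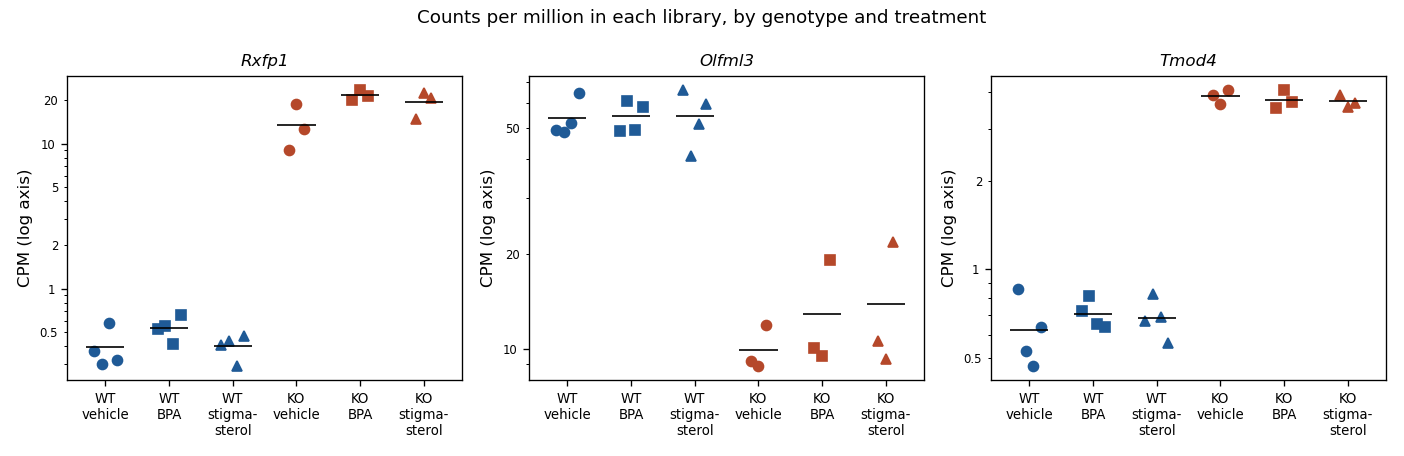
Rxfp1, Olfml3 and Tmod4 in CPM on log axes, 1 dot per library (blue WT, red KO; circle vehicle, square BPA, triangle stigmasterol), with a black line at each group's mean. In every treatment all KO libraries lie on 1 side of all WT libraries, with Olfml3 between 8.85 and 21.9 CPM in KO and between 41 and 66.2 CPM in WT.

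Markers of Sertoli cells, the somatic cells that support germ cells, were lower on average in KO vehicle testes. Their score, the mean log2 CPM of the list's members relative to all libraries, overlapped between the groups. It was -0.12 to 0.44 in WT vehicle and -0.07 to -0.04 in KO vehicle animals. Of 26 markers tested, 3 had a positive log2 fold change (median -0.38), and 5 fell over all genes tested (12 adjusted over the list alone). They include Gstm6 (-0.59 ± 0.138, adjusted p = 0.0258), Rhox8 (-0.51 ± 0.121, 0.0273), the hedgehog ligand Dhh (-0.63 ± 0.154, 0.0314) and the steroidogenic factor Nr5a1 (-0.45 ± 0.11, 0.0321). The camera adjusted p of the list was 1.78e-05, and it was 0.952 with an estimated correlation, as it was for each of the other lists called here. Each of those 4 genes lost its call without WT vehicle animal T81 or KO vehicle animal T1, T90 or T110, with adjusted p up to 0.11, 0.114, 0.125 and 0.0997, and Rhox8 also without WT vehicle animal T66 (0.0559). WT vehicle animal T81 and KO vehicle animals T1 and T110 are among the libraries with Cdh16 at 10 CPM or more. Without those libraries the Sertoli list was still called (0.0269; range over the alternatives other than left-out animals 3.66e-05 to 0.952).

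Genes of meiotic prophase had positive log2 fold changes in KO for 33 of 34 members (median 0.57, camera adjusted p = 0.000905, adjusted p = 0.952 with an estimated correlation), and 0 passed by edgeR over all genes or over the list alone. Tex14, Tex11 and Tex15, germ cell factors, had log2 fold changes of 0.45, 0.56 and 0.8 (adjusted p = 0.158, 0.197 and 0.221). Without WT vehicle animal T81 the list had an adjusted p of 0.127. The list's score, the mean log2 CPM of its members relative to all libraries, was -1.21 to 0.71 in WT vehicle and 0.03 to 0.97 in KO vehicle animals. Of its variance over all libraries, 21% lay between the 6 groups. Cholesterol biosynthesis genes had a median of -0.15 with 6 of 26 positive (camera adjusted p = 0.000905, adjusted p = 0.952 with an estimated correlation), and Pmvk (-0.38 ± 0.0946, adjusted p = 0.036) and Fdft1 (-0.31 ± 0.0807, 0.0406) fell (4 genes adjusted over the list alone). Immediate early and heat shock genes had a median of -0.25 (camera adjusted p = 0.00188, adjusted p = 0.952 with an estimated correlation), with Hspa1a (-1.02 ± 0.183, 0.00353) and Klf6 (-0.37 ± 0.0875, 0.0294) lower and 6 called adjusted over the list alone. Of the 7 fits that left out 1 library, Pmvk was called in 3 (highest adjusted p 0.131), Klf6 in 2 (0.109), Fdft1 in 1 (0.143) and Hspa1a in all 7.

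The 12 mitochondrially encoded oxidative phosphorylation genes had 0 positive members (median -0.17, camera adjusted p = 0.00766, adjusted p = 0.952 with an estimated correlation), and mt-Nd1 fell (-0.33 ± 0.0856, 0.0457; 1 gene adjusted over the list alone). That list was not called without WT vehicle animal T66 (0.114) or KO vehicle animal T110 (0.201). Epididymis and efferent duct markers had 10 of 11 positive (median 0.85, camera adjusted p = 0.0422, adjusted p = 0.952 with an estimated correlation), with Epcam higher (0.85 ± 0.212, 0.0346; 2 genes adjusted over the list alone). This list was not called without WT vehicle animal T66 (0.0938), T71 (0.0867) or T79 (0.103) or KO vehicle animal T1 (0.267) or T110 (0.0833). Of the 7 fits that left out 1 library, mt-Nd1 and Epcam were each called in 1 (highest adjusted p 0.122 and 0.142). Cdh16 is a member of the epididymis list, so leaving out libraries by Cdh16 does not test that list independently. Without the 9 Cdh16 libraries the adjusted p was 0.38 for meiotic prophase, 0.472 for cholesterol biosynthesis, 0.0826 each for the immediate early and mitochondrial lists and 0.31 for the epididymis list. Outside called lists, the germ cell factor Utf1 (1.31 ± 0.24, 0.00446) and the meiotic cyclin Ccna1 (1.63 ± 0.288, 0.00319) rose, and the MHC class II gene H2-Eb1 (-1.55 ± 0.271, 0.0029) fell, in all 7 fits with 1 library left out. Without the Cdh16 libraries none of the 3 was called (1.1, adjusted p = 0.491; 1.15, 0.662; and -1.57, 0.369), and Ccna1 was not with only these groups fitted (0.0592).

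Among known FXR targets, Apoc2, an activator of lipoprotein lipase, fell (-4.37 ± 0.964, 0.0187), a call lost without KO vehicle animal T1 (0.0562), T90 (0.0868) or T110 (0.0719). Over all treatments Apoc2 lay at 0.177 to 1.74 CPM in WT libraries and at 0 to 0.114 CPM in KO libraries. The KO values are near the floor of detection, so the size of its fold is uncertain. Nr0b2, the nuclear receptor SHP, had a log2 fold change of -0.77 ± 0.291 (adjusted p = 0.143). The bile acid transporter genes Slc51a and Slc51b had 0.97 ± 0.432 (0.211) and -0.27 ± 0.297 (0.636), and Nr0b1 had 0.01 ± 0.195 (0.991). None of these 4 passed in the vehicle groups.

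Pseudogenes made up 29.9% of the called genes that differed at least 2-fold, against 4.1% of the genes tested. Called genes that differed at least 2-fold also lay in blocks: 16 of the 49 tested genes between 175 and 180 Mb on chromosome 2, 11 of 104 between 40 and 45 Mb on chromosome 4, and 10 of 104 between 35 and 40 Mb on chromosome 17. With called genes of any fold, 4 of 84 tested genes within 5 Mb of Nr1h4 were called (4.8%), and between 5 and 20 Mb 6 of 300 (2%), against 3% on the other chromosomes. With genotype averaged over treatments these were 19 of 84 (22.6%) and 32 of 300 (10.7%), against 14%, a higher share in the nearest 5 Mb that was not tested. The count of 592 moved to 1413 with DESeq2 and to 185 when only these 2 groups were fitted. It moved to 242 without KO vehicle animal T1, 307 without T90 and 299 without T110, and to 269 without WT vehicle animal T81 and 986 without T79. Without the 9 libraries with Cdh16 at 10 CPM or more it was 56 (34 higher, 22 lower). Rxfp1 (5.46, adjusted p = 6.9e-05), Olfml3 (-2.51, 0.00427), Tmod4 (2.54, 0.00871), Akt2-ps (5.86, 0.0137), H2-Q10 (-5.34, 0.00337), Ccnd3-ps (5.63, 0.0133), Ppm1n (2.59, 0.0128), Shisa7 (-2.13, 0.0221) and Pianp (2.41, 0.0404) were still called there. The other called genes named for the vehicle groups were not, among them Dhh (-0.42, 0.985), Apoc2 (-4.86, 0.638), Lta (2.59, 0.181) and Slc2a2 (-2.76, 0.414). For the last 3 the fold stayed near its value in all libraries, so the loss of the call goes with the single KO vehicle animal left. Over all alternatives other than left-out animals, the adjusted p of Rxfp1 ranged from 8.16e-66 to 9.94e-05 and that of Dhh from 0.00321 to 0.985.

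Averaging the genotype effect over the 3 treatments gave 2820 called genes, 1388 higher and 1432 lower in KO (n = 12 WT and 9 KO), and 540 of them differed at least 2-fold (384 higher, 156 lower). Rxfp1 rose by 5.34 ± 0.151 (adjusted p = 1.36e-14), and Olfml3 (-2.16 ± 0.163, 3.46e-08), Slc2a2 (-3.06 ± 0.265, 2.42e-07) and Shisa7 (-2.16 ± 0.157, 2.15e-08) fell. The other large falls were Eps8l1 (-2.76), Hba-a2 (-2.49 ± 0.401), the mitochondrial arginine tRNA gene mt-Tr (-2.21 ± 0.309), H2-Q10 (-2.16 ± 0.313), Rimbp2 (-2.1) and Prph2 (-1.79), with adjusted p from 1e-04 to 0.00303. Hba-a1, the near-identical copy of Hba-a2, lay at 2.93 to 20.4 CPM in WT and 7.38 to 42.4 CPM in KO libraries. The Hba-a2 fall is thus not shown to be one of α-globin as a whole. The H2-Q10 fall did not hold in every treatment: KO BPA animals had 64.9 to 77.9 CPM, within the WT range of 46.3 to 89.6 CPM. KO stigmasterol animals T10, T15 and T93 had 2.16, 34.7 and 40.8 CPM. The other large rises were Akt2-ps (5.37 ± 0.296, 3.45e-10), Ccnd3-ps (5.32 ± 0.666, 2.75e-05), Car3 (4.16 ± 1.01, 0.0108), Npy6r (3.92, 0.0131), Wfdc15b (3.82, 0.0305), the keratin Krt5 (3.66, 0.0429), the defensin Defb1 (3.65 ± 0.843, 0.00773), Eif5al3-ps (3.57, 0.0368) and Spink8 (3.54, 0.0449). Car3, Npy6r, Wfdc15b, Krt5, Defb1, Eif5al3-ps and Spink8 all lost their calls in limma-voom (adjusted p from 0.0721 to 0.409) and with the epididymis score as covariate (0.115 to 0.929), where Krt5 turned to -0.47. Car3 turned to -2.86 without the 9 Cdh16 libraries (0.499). Car3 also lost its call without KO BPA animal T117 (2.84, adjusted p = 0.0548) or KO stigmasterol animal T10 (2.69, 0.201). Of the 21 fits that left out 1 library, Wfdc15b was called in 15 (highest adjusted p 0.107), Eif5al3-ps in 8 (0.769, without KO stigmasterol animal T93), Krt5 in 6 (0.248, without KO BPA animal T117) and Spink8 in 5 (0.117, without KO BPA animal T117). Eif5al3-ps is a processed copy of a translation factor gene, so its reads are of uncertain origin.

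Cholesterol biosynthesis genes, targets of the sterol sensor SREBP2, were lower in KO across treatments. Of 26, 15 fell and 1 rose over all genes tested (20 adjusted over the list alone), with a median of -0.2. Hmgcs1 fell by 0.49 ± 0.081 (adjusted p = 0.000508) and stood at 281 ± 17.4 CPM in KO vehicle (SD, n = 3) and 402 ± 83.4 CPM in WT vehicle (SD, n = 4). Fdft1 fell by 0.24 ± 0.0466 (0.00213) and Fdps by 0.23 (0.00326). The list's camera adjusted p was 1.43e-07, and its adjusted p = 0.841 with an estimated correlation, as for each other list called in this contrast. The fry test, which asks whether the genes move on balance 1 way, gave an adjusted p of 0.00704. The cholesterol call held whichever library was left out, and without the Cdh16 libraries its adjusted p was 0.00994 (range over the alternatives other than left-out animals 2.45e-07 to 0.841).

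Sertoli cell markers fell with them: 11 of 26 were lower and 0 higher (17 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 1.34e-06, adjusted p = 0.841 with an estimated correlation, fry adjusted p = 0.0234). Examples are Nr5a1 (-0.33 ± 0.0633, 0.00196), Dhh (-0.44 ± 0.0885, 0.00303), the male sex-determination factor Sox9 (-0.31 ± 0.0692, 0.00628) and Rhox8 (-0.3, 0.00727). The junction gene Gja1 (-0.59 ± 0.116, 0.00248) and the tight junction genes F11r (-0.27, 0.00548) and Ocln (-0.32, 0.0189) also fell. Mitochondrially encoded genes had 5 of 12 lower (8 adjusted over the list alone; median -0.19, camera adjusted p = 9.02e-05, adjusted p = 0.841 with an estimated correlation, fry adjusted p = 0.0234), among them mt-Nd1 (-0.27, 0.00145), mt-Atp8 (-0.23, 0.00163) and mt-Nd2 (-0.26, 0.0037). Both list calls held in all 21 fits that left out 1 library.

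Markers of epididymis and fat were higher in KO, with Cdh16 at 10 CPM or more in 6 of the 9 KO libraries. Epididymis and efferent duct genes were positive for 11 of 11 (median 0.87, 5 called, 6 adjusted over the list alone; camera adjusted p = 0.00711, adjusted p = 0.841 with an estimated correlation), with Epcam (0.87 ± 0.122, 0.000105), Cldn7 (1.21, 0.0185) and Cldn4 (1.72, 0.028) higher. Cldn4 was at 0 without the Cdh16 libraries. It lost its call without KO vehicle animal T1 (0.0669), KO BPA animal T117 (0.0838) or KO stigmasterol animal T93 (0.0736), and Cldn7 without the last of these (0.0565). Fat genes were positive for 13 of 15 (median 0.81, 7 called, 9 adjusted over the list alone; camera adjusted p = 0.0193, adjusted p = 0.841 with an estimated correlation), with Fabp4 (2.52 ± 0.545, 0.00495) and Adipoq (2.59 ± 0.585, 0.00658) higher. The fat list was not called without KO vehicle animal T1 (0.0515), KO BPA animal T117 (0.149) or KO stigmasterol animal T10 (0.0523). With the epididymis score as covariate the fat list was not called (camera adjusted p = 0.338). That covariate is the epididymis list's own score, so the loss of that list's call there (0.83) was set in advance. Without the 9 Cdh16 libraries, which leaves 1 KO animal per treatment, neither list was called. Cdh16 is a member of the epididymis list, so leaving out libraries by it does not test that list independently either.

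Meiotic prophase genes were positive for 32 of 34 (median 0.34, 0 called over all genes or over the list alone; camera adjusted p = 0.00881, adjusted p = 0.841 with an estimated correlation). That call was lost without WT vehicle animal T81 (0.0697), WT stigmasterol animal T78 (0.074), KO vehicle animal T1 (0.0515), KO BPA animal T25 (0.125) or KO stigmasterol animal T10 (0.0641), or without the 2 libraries with liver transcripts (0.0538). Immediate early and heat shock genes had a median of -0.13, with 4 lower and 1 higher (6 adjusted over the list alone; camera adjusted p = 0.0346, adjusted p = 0.841 with an estimated correlation), including Klf6 (-0.29, 0.000868), Hspa1a (-0.56, 0.0016) and Jund (-0.36, 0.00993). That call was lost without WT vehicle animal T79 (0.0835), WT BPA animal T60 (0.0562), KO vehicle animal T1 (0.0515) or T110 (0.0577), KO BPA animal T25 (0.125) or KO stigmasterol animal T10 (0.0929).

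Single genes of lists that were not called also differed. The meiotic cyclin Ccna1 rose (1.45 ± 0.166, 9.95e-06), as did the germ cell factor Pou5f1 (0.69, 0.000341), the retinoid-binding protein gene Crabp2 (1.03 ± 0.179, 0.000881) and the transporter gene Abcc3 (1.18 ± 0.214, 0.00125). The piRNA-pathway gene Piwil1 (-0.57 ± 0.0853, 0.000192), the interferon-induced Rsad2 (-1.07 ± 0.155, 0.000144), the estrogen-responsive Greb1 (-0.97 ± 0.211, 0.00533) and the lipoprotein receptor gene Scarb1 (-0.37, 0.000968) fell. Of the FXR targets, Apoc2 fell by 4.02 ± 0.528 (4.79e-05) and Slc51a rose by 0.82 ± 0.247 (0.0334), while Nr0b2 (-0.26, 0.33), Slc51b (-0.13, 0.673) and Nr0b1 (-0.13, 0.499) did not pass. Apoc2 was near the floor of detection in KO libraries, at 0 to 0.114 CPM, so the size of its fold is uncertain. The Slc51a call held in 11 of the 21 fits that left out 1 library (highest adjusted p 0.0876, without KO BPA animal T25). Without the 9 Cdh16 libraries Rxfp1, Akt2-ps, Ccnd3-ps, Slc2a2, Eps8l1, Hba-a2, mt-Tr, Shisa7, Olfml3, H2-Q10, Pou5f1, Ccna1 and Epcam kept their calls in this contrast. The other called genes named for it did not or were below the filter there, among the former Nr5a1 (-0.32, adjusted p = 0.204), Sox9 (-0.35, 0.175), Rhox8 (-0.22, 0.502), Hmgcs1 (-0.4, 0.201), Piwil1 (-0.48, 0.161), Greb1 (-1.13, 0.201), Abcc3 (0.47, 0.206) and Fabp4 (0.21, 0.857). The count of 2820 moved to 1701 without the 2 WT BPA libraries with liver transcripts and to 257 (138 of them lower) without the 9 Cdh16 libraries. Of the genes called in the vehicle groups, 541 were called here too, all in the same direction.

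In WT animals, BPA against vehicle asks what BPA does with the receptor present. By edgeR 0 genes passed (smallest adjusted p = 0.0609, shared by the 10 genes that follow), with 3798 genes at an unadjusted p under 0.05, while DESeq2 called 1040 (289 higher, 751 lower) and limma-voom 1488 (496 higher, 992 lower). The smallest p belonged to Mir143hg, the host transcript of a smooth muscle microRNA, at 2.64 ± 0.66 CPM in vehicle and 6.97 ± 2.27 CPM in BPA (SD, n = 4 each; log2 fold change 1.4 ± 0.239). Hint1 was at 150 ± 4.74 CPM in vehicle and 118.9 ± 8.22 CPM in BPA (-0.33 ± 0.0577). The others were the proteasome gene Psmc4 (-0.26 ± 0.0468), Mir143 (1.96 ± 0.381), the initiation factor gene Eif1 (-0.31 ± 0.0613), Rbm33 (0.27 ± 0.0536), the cytokine receptor gene Il31ra (0.91 ± 0.18), Trim27 (-0.25 ± 0.0498), Tmem261 (-0.46 ± 0.0912) and the ribosomal protein gene Rpl31 (-0.25 ± 0.0492). Mir143 lies within Mir143hg, so their reads overlap. The groups did not overlap for 1640 genes, 8.1% of those tested, where chance gives 2.9%.

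Sertoli cell markers were lower in BPA-treated WT testes by the list test. The list's score overlapped between the groups, at -0.25 to 0.2 in WT BPA and -0.12 to 0.44 in WT vehicle animals. Of 26 markers, 2 were positive (median -0.32) and 10 passed adjusted over the list alone, 1 of them higher (camera adjusted p = 3.8e-05, adjusted p = 0.704 with an estimated correlation). Rhox8 (-0.43, adjusted p = 0.0741), Aard (-0.46, 0.0776) and the defensin Defb19 (-0.81, 0.0861) had the smallest p. The androgen-responsive genes had 3 of 14 positive (median -0.21, 2 adjusted over the list alone; camera adjusted p = 0.033, adjusted p = 0.704 with an estimated correlation), and Sertoli junction genes had a median of -0.11 (2 adjusted over the list alone; 0.0462, adjusted p = 0.704 with an estimated correlation). Tubb3 (-0.6) and Jam3 (-0.27) had the smallest p of those 2 lists. Cholesterol biosynthesis genes had a median of -0.09 (camera adjusted p = 0.0469, adjusted p = 0.719 with an estimated correlation), with Ebp at -0.5 and Fdft1 at -0.17.

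Peritubular myoid and smooth muscle genes were positive for 14 of 14 members (median 0.4, camera adjusted p = 0.0106, adjusted p = 0.704 with an estimated correlation), and extracellular matrix genes for 25 of 29 (median 0.28, 0.00629, adjusted p = 0.771 with an estimated correlation). Actg2 and Cnn1, contractile proteins, were at 1.42 and 0.99, and Col12a1 and Fn1 at 1.91 and 0.47. Genes of the piRNA pathway and DNA methylation were positive for 24 of 26 (median 0.21, 0.000799, adjusted p = 0.704 with an estimated correlation), with Morc1 at 0.41, and undifferentiated spermatogonia genes for 19 of 24 (median 0.2, 0.0244, adjusted p = 0.704 with an estimated correlation), with Neurog3 at 0.56 and Zbtb16 at 0.39. FXR target genes were positive for 21 of 25 (median 0.49, 4 adjusted over the list alone; camera adjusted p = 0.0244, adjusted p = 0.704 with an estimated correlation), led by Apoa1 (5.83), Kng1 (6.53) and Pck1 (1.8). Apoa1 and Kng1 are also liver transcripts and were at 82.3 and 20.9 CPM in WT BPA animal T61, where Alb was 578 CPM. Without WT BPA animals T61 and T75 the FXR target list had a median of -0.01 and an adjusted p of 0.955 (range over the alternatives other than left-out animals 0.0231 to 0.955).

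With 1 library left out, the Sertoli call held in all 8 fits. The calls lost without 1 vehicle animal were extracellular matrix without animal T66 (0.0624) or T71 (0.124), myoid without T71 (0.0504), androgen-responsive without T66 (0.0624) or T71 (0.0724), junctions without T71 (0.0606) or T81 (0.24), FXR targets without T79 (0.085), piRNA without T81 (0.089), undifferentiated spermatogonia without T81 (0.201), and cholesterol without T79 (0.237) or T81 (0.154). The calls lost without 1 BPA animal were extracellular matrix (0.0643), myoid (0.0945), androgen-responsive (0.0573), junctions (0.0915) and cholesterol (0.0946) without animal T75, undifferentiated spermatogonia without T60 (0.0758) or T61 (0.0904), FXR targets without T61 (0.411), junctions without T60 (0.0764) or T74 (0.0748), and cholesterol without T74 (0.164). The count of 0 called genes moved to 1321 (403 higher, 918 lower) without WT vehicle animal T79, to 279 (111 higher, 168 lower) without WT BPA animal T60 and to 15 without WT BPA animal T74. Without the 2 libraries with liver transcripts it was 0, with 2025 genes at an unadjusted p under 0.05, and the undifferentiated spermatogonia (0.0505) and androgen-responsive (0.05) lists were not called. With the epididymis score as covariate the myoid (0.0852), cholesterol (0.137) and matrix (0.0515) lists were not called. With the meiotic score as covariate the test called 1195 genes.

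Stigmasterol against vehicle in WT animals asks the same of the plant sterol. Rpl31, a gene of the large ribosomal subunit (ENSMUSG00000073702, chromosome 1, 39367851 to 39371908), fell from 164 ± 3.54 to 128 ± 4.81 CPM (SD, n = 4 each; log2 fold change -0.36 ± 0.0493, adjusted p = 0.0174) and was the 1 gene called by edgeR. Other genes with a small p also belong to the ribosome: Rps27rt (-0.28, adjusted p = 0.129), Rps14 (-0.33), Rpl36 (-0.29), Rps15 (-0.33), Rpl17 (-0.28), Rpl37a (-0.29) and Rps27 (-0.32), the last 6 with an adjusted p of 0.205 each. Gabarap (-0.22, 0.205), an autophagy gene, was also among the smallest p. Ribosomal protein genes have many processed copies, so part of their reads is of uncertain origin. Over all 82 tested cytosolic ribosomal protein genes, a list chosen after these values were seen, the median log2 fold change was -0.232 with stigmasterol and -0.187 with BPA in WT, and all 82 were negative in both, with 1 and 0 of them called. The Rpl31 call was lost with no filter (0.0887), when only these 2 groups were fitted (0.978) and with a gene length trend removed (-0.32, 0.0846), over a range of 1.74e-07 to 0.978. It was also lost without WT vehicle animal T66 (0.0935), T71 (0.0641), T79 (0.104) or T81 (0.0749) or WT stigmasterol animal T98 (0.123), T118 (0.156) or T119 (0.0927). At an unadjusted p under 0.05 there were 1672 genes, DESeq2 called 84 and limma-voom 8, and none of the 30 fixed lists was called.

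**Figure D3:**
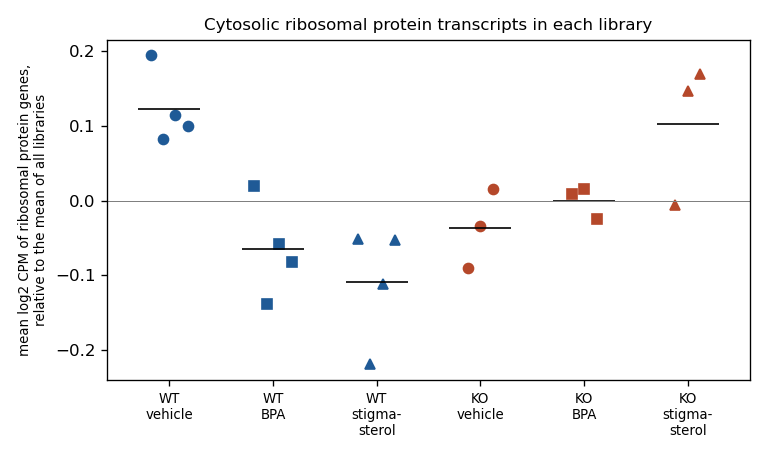
Mean log2 CPM of the ribosomal protein genes relative to their mean over libraries, 1 dot per library (blue WT, red KO; circle vehicle, square BPA, triangle stigmasterol), with a black line at each group's mean. The WT vehicle libraries lie at 0.082 to 0.194 and the WT stigmasterol libraries at -0.219 to -0.051.

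BPA against vehicle in KO animals asks what BPA does without the receptor. The cytokine genes Ltb and Lta fell and H2-Q10 rose, and these were the 3 genes called. Ltb (ENSMUSG00000024399, chromosome 17, 35194439 to 35196320) fell from 4.35 ± 0.485 to 0.918 ± 0.134 CPM (SD, n = 3 each; log2 fold change -2.24 ± 0.232, adjusted p = 0.000246), and Lta from 1.41 ± 0.206 to 0.154 ± 0.0449 CPM (-3.17 ± 0.379, 0.00111). H2-Q10 rose from 1.86 ± 0.212 to 70.2 ± 6.81 CPM (5.24 ± 0.654, 0.00137), against 72 ± 18.9 CPM in WT vehicle (SD, n = 4). Within KO stigmasterol, H2-Q10 was 2.16 CPM in animal T10, 34.7 CPM in animal T15 and 40.8 CPM in animal T93. The next genes by p were Cchcr1 (0.47, adjusted p = 0.256), Vps52 (-0.42, 0.394), Pgam2 (-0.89, 0.489), the macrophage gene Aif1 (-1.11, 0.489), Lrfn2 (2.13, 0.489), H2-Eb1 (1.26, 0.513) and Atp6v1g2 (0.78, 0.513). Of these 10, 8 lie on chromosome 17. Lta and Ltb lost their calls when only these 2 groups were fitted (0.054 and 0.0504, the highest of their alternatives). The count of 3, with 873 genes at an unadjusted p under 0.05, moved to 12 without KO BPA animal T117. DESeq2 called 12 and limma-voom 4.

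**Figure D4:**
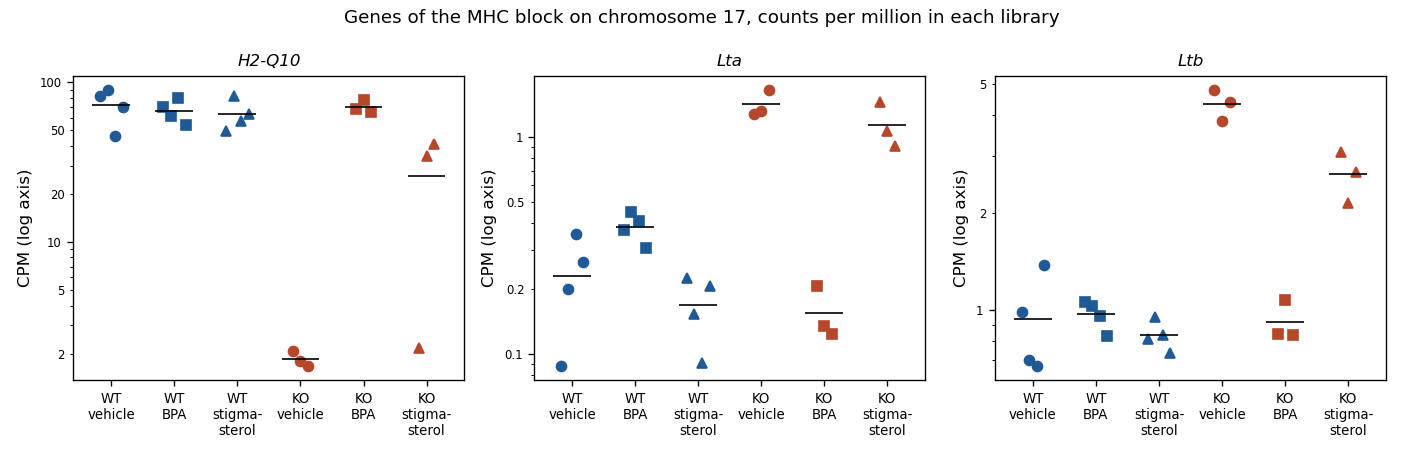
H2-Q10, Lta and Ltb in CPM on log axes, 1 dot per library (blue WT, red KO; circle vehicle, square BPA, triangle stigmasterol), with a black line at each group's mean. KO vehicle libraries lie at 1.67 to 2.09 CPM of H2-Q10 and KO BPA libraries at 64.9 to 77.9 CPM, with KO stigmasterol libraries from 2.16 to 40.8 CPM.

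Meiotic prophase genes had lower values in KO BPA than in KO vehicle for all 34 members (median -0.6, 0 positive; camera adjusted p = 1.3e-07, adjusted p = 0.912 with an estimated correlation), with Tex15 at -0.84, Ythdc2 at -0.52 and Meiob at -1.61. These members are not independent observations. The list's score overlapped between the groups, at -0.81 to 0.55 in KO BPA and 0.03 to 0.97 in KO vehicle animals, and 21% of its variance lay between the 6 groups. Late spermatocyte and spermatid genes had a median of -0.27 (0.0117, adjusted p = 0.632 with an estimated correlation), with Tcp11 at -0.62, and androgen-responsive genes of -0.18 (0.0045, adjusted p = 0.575 with an estimated correlation), with Rhox5 at -1.33. Extracellular matrix genes were positive for 29 of 29 (median 0.27, 0.00384, adjusted p = 0.912 with an estimated correlation), with Mmp2 at 0.55 and Col12a1 at 1.09 (-0.25 without KO BPA animal T117), and myoid genes for 14 of 14 (median 0.28, 0.0385, adjusted p = 0.912 with an estimated correlation). Endothelial genes had a median of 0.19 (0.0143, adjusted p = 0.912 with an estimated correlation), and immediate early genes of 0.18 (0.00121, adjusted p = 0.575 with an estimated correlation), with Cyr61 at 0.82 and Fosb at 1.3. KO BPA animal T117, which had the fat transcripts Car3 and Fabp4 at 33.6 and 35.8 CPM, carried part of this: without it the adjusted p was 0.954 for matrix, 0.675 for endothelium, 0.457 for myoid genes, whose direction turned, and 0.159 for the late germ cell list. The meiotic and androgen lists kept their calls in all 6 fits. The matrix call was also lost without KO vehicle animal T1 (0.117), the endothelial without T90 (0.107), the myoid without T90 (0.43) or T110 (0.0533), and the immediate early without KO BPA animal T83 (0.117).

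Stigmasterol against vehicle in KO animals gave 0 called genes in edgeR, with 779 at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma-voom. The smallest p belonged to H2-Q10 (log2 fold change 3.8 ± 0.627, adjusted p = 0.18), which DESeq2 called (3.81, 3.53e-06). The next were Paqr6 (0.52), the muscle gene Neb (-0.56), Tspan8 (-0.81), Rps27rt (0.24), Brinp3 (2.85), Cyr61 (0.84), Ptpn7 (-0.78), Chrnb1 (0.55) and Hoxb9 (0.83), each with an adjusted p of 0.981. Cholesterol biosynthesis genes were positive for 3 of 26 (median -0.12, camera adjusted p = 1.92e-06, adjusted p = 0.963 with an estimated correlation), with Srebf2, the gene of the sterol regulator itself, at -0.19 and Cyp51 at -0.2. Leukocyte genes had a median of -0.21 (0.00688, adjusted p = 0.963 with an estimated correlation), with Lyz2 at -0.61 and H2-Eb1 against the list at 0.76, and undifferentiated spermatogonia genes of -0.12 (0.0452, adjusted p = 0.963 with an estimated correlation), with Utf1 at -0.8. The cholesterol call was lost without KO stigmasterol animal T93 (0.0895), which had 203 CPM of Cdh16. The leukocyte call was lost without KO vehicle animal T1 (0.0548) or T110 (0.14) or KO stigmasterol animal T10 (0.342), and the spermatogonia call without KO vehicle animal T90 (0.176) or T110 (0.14) or KO stigmasterol animal T10 (0.502). With the epididymis score as covariate the spermatogonia list had an adjusted p of 0.155. The count was 1 without KO stigmasterol animal T10 or T15, and 3 with the meiotic score as covariate.

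The BPA by genotype interaction tests whether BPA acts differently with and without FXRα. Lta (-3.92 ± 0.502, adjusted p = 0.00532), Ltb (-2.29 ± 0.306, 0.00532) and H2-Q10 (5.35 ± 0.774, 0.0106) were called, the same 3 genes as within KO. Ifi35 (0.68), Cchcr1 (0.53), Tomm5 (0.62), Rpl31 (0.32), Ring1 (0.6), Lrfn2 (2.38) and Cox7c (0.36) followed, each with an adjusted p of 0.536. H2-Q10 lost its call without KO vehicle animal T1 (0.0847), T90 (0.108) or T110 (0.0993), and all 3 genes did without the 2 WT BPA libraries with liver transcripts, where the count was 0. There Lta was at -3.74 (0.074), Ltb at -2.26 (0.074) and H2-Q10 at 5.45 (0.144), the highest adjusted p of their alternatives. The folds stayed near their values in all libraries, so the loss goes with the 2 WT BPA animals left. At an unadjusted p under 0.05 there were 1788 genes, DESeq2 called 8 and limma-voom 3, and leaving out KO BPA animal T117 gave 5.

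By list, the BPA effect was higher in KO than in WT for Sertoli markers, positive in 21 of 26 (median 0.31, camera adjusted p = 0.00125), and for immediate early and heat shock genes, positive in 24 of 25 (median 0.2, 0.000479). It was lower for piRNA and DNA methylation genes (median -0.25, 0.000697), meiotic prophase (-0.33, 0.00554), pluripotency (-0.27, 0.00938) and undifferentiated spermatogonia (-0.16, 0.0189). Each of these 6 lists had an adjusted p of 0.907 with an estimated correlation. Rhox8 (0.46), Hspa1a (0.99), Piwil1 (-0.45), Tex15 (-1.05) and Utf1 (-1.28) are examples. The Sertoli, immediate early and piRNA calls held in all 14 fits that left out 1 library. The meiotic call was lost without WT vehicle animal T79 (0.0588) or T81 (0.285), KO vehicle animal T1 (0.142) or KO BPA animal T117 (0.26), and the pluripotency call without WT vehicle animal T81 (0.106), KO vehicle animal T90 (0.0539) or KO BPA animal T117 (0.0645). The spermatogonia call was lost without WT vehicle animal T81 (0.141), WT BPA animal T60 (0.0542) or T61 (0.0893), KO vehicle animal T90 (0.0548), or KO BPA animal T25 (0.138) or T117 (0.0645), or without the 2 libraries with liver transcripts (0.0542).

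The stigmasterol by genotype interaction called Rpl31 (0.56 ± 0.0751, adjusted p = 0.012) and Rps27rt (0.52 ± 0.0752, 0.0151), ribosomal protein genes whose levels were lower with stigmasterol in WT and higher in KO. Rps27rt (ENSMUSG00000050621, chromosome 9, 114982371 to 114982740) was at 115 ± 4 and 94.3 ± 1.78 CPM in WT vehicle and stigmasterol (SD, n = 4 each) and at 112 ± 2.97 and 132 ± 1.75 CPM in KO (SD, n = 3 each). Others with a small p were Pag1 (-0.58, 0.0761), Rpl17 (0.48, 0.0761), Rpl37a (0.49, 0.0897), H2-Q10 (4, 0.116), Paqr6 (0.81, 0.116), Rps15 (0.49, 0.135) and Rpl37 (0.48, 0.135). Over the 82 ribosomal protein genes, which include Rpl31 but not Rps27rt, the median was 0.383 and 1 gene was called. Leukocyte (median -0.25), cholesterol (-0.14) and piRNA lists (-0.15) each had a camera adjusted p of 0.0457 and an adjusted p of 0.993 with an estimated correlation, with Cd163 at -0.79, H2-Eb1 against its list at 0.89, and Tdrd1 at -0.26. Of 14 fits that left out 1 library, 7, 8 and 6 kept these calls (highest adjusted p 0.386, 0.683 and 0.692), and with the epididymis score as covariate the cholesterol (0.272) and piRNA (0.366) lists were not called. Rpl31 lost its call without KO vehicle animal T1 (0.103) or T90 (0.0523) or KO stigmasterol animal T15 (0.101) or T93 (0.0545). Rps27rt lost its call without the same animals and without KO vehicle animal T110 (0.0556). At an unadjusted p under 0.05 there were 1855 genes. DESeq2 called 136, limma-voom 15, edgeR with no filter or with only these groups 0, and edgeR with the meiotic score as covariate 25. The count of 2 was 11 without KO stigmasterol animal T10, 6 without WT stigmasterol animal T78, 1 without KO vehicle animal T110, and 0 without KO vehicle animal T1 or T90 or KO stigmasterol animal T15 or T93.

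Across the tested genes, which are not independent replicates, the BPA effects in WT and KO had a Pearson correlation of 0.15 (Spearman 0.16, same sign in 55.2%), and the stigmasterol effects -0.21 (Spearman -0.26, same sign in 38.9%). These pairs share no library, and simulated groups with no effect gave 0. BPA and stigmasterol effects share their controls: in WT their correlation was 0.25 where simulation with no effect gave 0.51, and in KO 0.32 against 0.5. The WT covariance was 0.037 against a simulated 0.05. Genes were drawn independently in these simulations too, so they do not cover genes that move together between animals. How far such correlations stray by chance is therefore not known, and the differences from the simulated values were not tested. With the WT vehicle animals split between both treatments, the 3 splits gave correlations of -0.09, -0.01 and 0. Leaving out 1 library moved the BPA correlation between genotypes from 0.15 to as low as -0.13, without KO BPA animal T117, and as high as 0.3, without KO vehicle animal T1. The stigmasterol correlation was -0.03 without WT vehicle animal T81 and -0.12 without KO stigmasterol animal T93. Of the genes at an unadjusted p under 0.05, 66 were higher with BPA in both genotypes where independent lists would share 39.2, and 32 were lower where 41.8 would be shared. With stigmasterol 4 were higher in both genotypes where 19.1 would be shared, and 1 was lower where 12.4 would be.

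The authors' deposited table gives their own adjusted p for the 4 treatment comparisons, rounded to 2 decimals. In it 965 genes had a value printed under 0.05 for BPA in WT (333 higher, 632 lower), 12 for stigmasterol in WT, 18 for BPA in KO and 5 for stigmasterol in KO. Of the 965 in the authors' deposited table, 901 were tested here and all had the same sign here, while 815 were also called by DESeq2, 745 by limma-voom and 0 by edgeR. Of the genes the authors' deposited table has under 0.05 for stigmasterol in WT 12 were tested here, with 12 called by DESeq2 and 4 by limma-voom, for BPA in KO 16, with 9 and 3, and for stigmasterol in KO 4, with 0 and 0. The log2 fold changes of the authors' table and those computed here had Pearson correlations of 0.99, 0.99, 1 and 0.99 across genes.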

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

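The tests of the sequence around Nr1h4, of epididymal RNA, of the ribosomal protein genes and of the MHC block were chosen after the results they test were seen. The test of strain haplotypes was set after the clusters were seen and before its own value was, and the search for a lone library was set before. A lone library was looked for in 501 groups of 4, as a value whose gap to its nearest neighbour takes most of the group's range, and 40 were found. Chance gives about 1 in 20 groups, 5 percent.

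The largest KO against WT differences lay in clusters along the chromosomes. Of 234 called genes that differed at least 2-fold, 109 (46.6%) had another within 1 Mb, against a median of 29.9% and a highest of 41.9% in 1000 random sets. The tables argue against sequence carried along with the targeted Nr1h4 locus as the cause of these clusters, since 2 of the clustered genes (1.8%) lay within 20 Mb of it. For single genes near the locus such sequence stays open, as 22.6% of those within 5 Mb were called in the averaged contrast against 14% on other chromosomes. The tables also argue against epididymal RNA, since 90 of them (82.6%) were still called with the epididymis score as covariate. Strain haplotypes that still segregate among animals of a mixed background are a candidate explanation: residuals of 170 neighbouring pairs correlated with a median of 0.26, against 0.03 (upper bound of the central 95% of values 0.1) for reshuffled positions and 0.02 for uncalled neighbours. That test cannot tell haplotypes apart from reads shared between neighbouring near-identical copies. Segregation within a genotype was also not seen at some of the largest differences. No KO library reached the WT range at Rxfp1 (WT 0.291 to 0.657 CPM, KO 9.08 to 23.6), Tmod4 (0.469 to 0.856, 3.54 to 4.08) or Olfml3 (41 to 66.2, 8.85 to 21.9). Loss of FXRα itself stays open for any single gene and was not tested apart from the haplotype. At genes where all KO animals differ from all WT animals, the design cannot tell it apart from a haplotype shared by all KO animals.

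In WT, the medians of 82 ribosomal protein genes were -0.187 with BPA and -0.232 with stigmasterol, against the same 4 vehicle animals, with 0 and 1 genes called. The list was chosen after these values were seen and had no test as a set. The stigmasterol interaction called Rpl31 (0.56, adjusted p = 0.012) and Rps27rt (0.52, adjusted p = 0.0151), calls lost in 4 and 5 of 14 fits that left out 1 library. Rps27rt is not in that list. The tables argue against a gene length trend as the whole cause, since genes matched on length and expression reached 37.6% of the ribosomal median in WT BPA (quartiles 30 and 49.1) and 4.6% in WT stigmasterol. They also argue against 1 unusual vehicle library, since at least 84.2% of the ribosomal median in WT BPA remained whichever WT vehicle library was left out. A response to the treatments, or a difference between the animals in the WT vehicle group and the rest, may remain, and neither was tested further.

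At the MHC block of chromosome 17, KO BPA and KO vehicle animals stood apart, and the BPA effect differed between genotypes for Ltb (-2.29, adjusted p = 0.00532), Lta (-3.92, adjusted p = 0.00532) and H2-Q10 (5.35, adjusted p = 0.0106). Haplotypes of this block segregating among KO animals are a candidate explanation. Across 188 genes of the block, the difference between KO stigmasterol animals T93 and T10, which had no BPA, correlated with the BPA effect in KO at 0.76, against a median of 0.29, an upper bound of the central 95% of 0.54 and a highest of 0.63 in 96 windows elsewhere. These 2 animals had the highest and lowest H2-Q10 of their group (40.8 and 2.16 CPM), and H2-Q10 is in the block. The pair was not extreme in this way for the windows, so the comparison may favour the block. A response to BPA cannot be told apart from such haplotypes: H2-Q10 had a log2 fold change of -0.12 with BPA in WT, and the highest KO stigmasterol animal, at 40.8 CPM, lay below the lowest KO BPA animal, at 64.9 CPM.

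WT vehicle animal T81 stood apart at several markers of neighbouring tissue, with 17.6 CPM of Cdh16 (others 0.1 to 0.38), 7.48 CPM of Spink8, 1.44 CPM of Wfdc15b, 0.666 CPM of Npy6r, 0.213 CPM of Defb1, 0.0532 CPM of Krt5 and 1.86 CPM of Fabp4, and with an epididymis score of 0.704. It also had 346 CPM of Nr5a1, 61.3 CPM of Tex14 (others 105 to 107) and a Leydig score of 0.472. The Krt5 value of animal T81 lies below that library's floor of 0.075 CPM. Krt5 and Defb1 had no read in the other WT vehicle animals. WT vehicle animal T79 had 117.8 CPM of Tubb3 and 25.3 CPM of Ebp, and animal T66 had 6.36 CPM of Paqr6.

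WT BPA animal T61 stood apart at liver transcripts, with 578 CPM of Alb, 82.3 CPM of Apoa1, 20.9 CPM of Kng1, 15.5 CPM of Pck1 and 1.74 CPM of Apoc2. It also had 228 CPM of Dhh, 90 CPM of Klf6 and 3.56 CPM of Guca1b. WT BPA animal T75 had 10.1 CPM of Eps8l1, and WT BPA animal T60 had 3.28 CPM of Eif5al3-ps (others 0.0217 to 0.0477).

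WT stigmasterol animal T98 had 0.303 CPM of Nr1h4 (others 0.547 to 0.582), 43 CPM of Erdr1 (others 0.203 to 1.24), 3.07 CPM of Spink8, 1.54 CPM of Fabp4, 0.758 CPM of Car3, 0.173 CPM of Wfdc15b, 0.152 CPM of Npy6r, 0.0866 CPM of Defb1 and an interferon score of 0.204. WT stigmasterol animal T78 had 118.2 CPM of Defb19 (others 245 to 257), 105 CPM of Zbtb16, 26.9 CPM of Ebp, 331 CPM of Srebf2, 5.13 CPM of Pianp and an undifferentiated spermatogonia score of 0.231. WT stigmasterol animal T119 had 13.3 CPM of Hba-a2.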

How the results depend on the processing

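The covariate scores, the length trend, the sets of libraries left out together and the left-out libraries of lists and agreement were chosen after the data were seen. KO against WT counts (592 in vehicle, 2820 averaged) stayed within 1.5 times of their value under DESeq2 size factors, no filter, limma-voom, animal number, a robust fit, both covariate scores and the length trend. The vehicle count was 1413 with DESeq2, 185 with only these groups and 56 without the 9 Cdh16 libraries, and 242 (without KO vehicle animal T1) to 986 (without WT vehicle animal T79) with 1 library left out. The averaged count was 1701 without the 2 libraries with liver transcripts and 257 without the Cdh16 libraries, which leaves 1 KO animal per treatment. BPA in WT (0 genes) gave 1040 with DESeq2, 1488 with limma-voom, 1 with animal number, 1195 with the meiotic score, and 0 to 1321 (without WT vehicle animal T79) with 1 library left out. Stigmasterol in WT (1 gene) gave 84 with DESeq2, 8 with limma-voom, 0 with no filter, only these groups or the length trend, and 0 to 1 with 1 library left out. BPA in KO (3 genes) gave 12 with DESeq2, 1 with only these groups, and 3 to 12 with 1 library left out. Stigmasterol in KO (0 genes) gave 1 with DESeq2, 1 with only these groups, 3 with the meiotic score, and 0 to 1 with 1 library left out. The BPA interaction (3 genes) gave 8 with DESeq2, 0 without the libraries with liver transcripts, and 2 to 5 with 1 library left out. The stigmasterol interaction (2 genes) gave 136 with DESeq2, 15 with limma-voom, 25 with the meiotic score, 1 with animal number, 0 with no filter or only these groups, and 0 to 11 with 1 library left out. Fits of only the compared groups and of fewer libraries have fewer animals to estimate the spread, and for the rest the cause was not tested.

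Of 41 list calls, 0 held with an estimated correlation, 3 with directional fry, 9 with mixed fry, 32 with the epididymis score, 6 of 13 without the Cdh16 libraries, 17 of 22 without the libraries with liver transcripts and 352 of 447 with 1 library left out. With the epididymis score as covariate, the epididymis list and its members, such as Cdh16, were set against their own score. Their losses there do not test them independently. The myoid list in KO BPA had an adjusted p of 0.000303 to 0.457 and turned to lower without KO BPA animal T117. Among values of named genes with 1 library left out, 2450 of 2697 kept their direction and side of the threshold and 4 changed direction. Without the Cdh16 libraries 37 of 108 did, 68 were no longer called and 3 changed direction. Nr0b1 in vehicle (0.01) was -0.11 with limma-voom, -0.01 with animal number, -0.05 with the epididymis score, -0.13 with the meiotic score, -0.06 without the Cdh16 libraries, and -0.14 to 0.1 with 1 library left out. In the averaged contrast Car3 was -2.86 and Cldn4 0 without the Cdh16 libraries, Krt5 -0.47 and Cdh16 -0.02 with the epididymis score, and Slc51b 0 with the meiotic score. Col12a1 with BPA in KO was -0.25 (without KO BPA animal T117) to 1.53. In genes of at least 10 CPM the correlation between genotypes was 0.24 for BPA and -0.39 for stigmasterol, and that of both treatments was 0.36 in WT and 0.48 in KO. With WT vehicle animals split it was -0.09, -0.01 and 0. With 1 library left out, BPA between genotypes gave -0.13 to 0.3, stigmasterol between genotypes -0.26 to -0.03, both treatments in WT 0.15 to 0.49 and in KO 0.21 to 0.51, and the cause was not tested. No paired analysis was possible because the groups share no animal numbers.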

Other observations

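The comparisons of genotype within each treated group, the ribosomal protein list and the liver list were chosen after the data were seen. The genotype difference was also measured within each treatment, where KO against WT called 174 genes among BPA animals and 1461 among stigmasterol animals by edgeR, and 124 of the genes called in vehicle were called in all 3 treatments. Of the 592 genes called in vehicle, 533 had the same sign in the BPA groups and 562 in the stigmasterol groups. Rxfp1 stood at 21.7 ± 1.74 CPM in KO BPA and 19.3 ± 3.92 CPM in KO stigmasterol (SD, n = 3 each), against 0.537 ± 0.1 and 0.4 ± 0.0776 CPM in the matching WT groups (SD, n = 4 each).

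The list of cytosolic ribosomal protein genes had no test as a set, and 0 or 1 of its 82 genes was called in each treatment or interaction contrast. Its median log2 fold change over 82 genes was -0.161 for KO against WT in vehicle, with 78 negative and 4 genes called, all lower. It was 0.028 for KO against WT averaged over treatments, with 10 genes called, all higher. Within KO it was 0.037 with BPA, with 22 of 82 negative, and 0.138 with stigmasterol, with 0 negative. The interaction medians were 0.218 for BPA and 0.383 for stigmasterol, with 0 negative in either. With a gene length trend removed, the medians were -0.118 for BPA in WT, -0.182 for stigmasterol in WT, 0.116 for stigmasterol in KO and 0.307 for the stigmasterol interaction.

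Of the 30 fixed lists, 18 were called by camera in at least 1 contrast and 12 in none. The lowest camera adjusted p of the latter over the 8 contrasts was 0.064 for differentiating spermatogonia (median 0.2 in KO vehicle against WT vehicle), 0.079 for retinoid metabolism and signalling, 0.0844 for proliferation, 0.0941 for skeletal muscle and 0.163 for Leydig cell steroidogenesis. It was 0.201 for blood, 0.262 for the interferon response, 0.263 for bile acid synthesis, receptors and transport, 0.309 for p53 targets and apoptosis, and 0.453 for estrogen receptors and estrogen-responsive genes. Xenobiotic metabolism reached 0.635 and LXR target genes 0.672. The liver list of 15 genes had a median of 5.83 for BPA against vehicle in WT with 0 called by edgeR, and -0.78 for KO against WT averaged over treatments.

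Other groupings of the same libraries, a planned test, were fitted for each count. For KO against WT in vehicle the real 592 genes was matched by 1 of 35 splits (2.86%), the real one. That is the smallest share these splits can give. The highest other split gave 529, so a wrong grouping of the same libraries called nearly as many. Chance is therefore not firmly excluded for this count. For the averaged genotype contrast the real 2820 stood alone among 100 splits drawn from 42875 (1 as large, highest other 12). None of the other splits drawn came near this count. The 3 genes of the BPA interaction were reached by 4 of 100 splits drawn from 700 (highest other 12). These genes are neighbours in 1 block, so whether chance can be excluded for them is left open. The 1 gene of stigmasterol in WT was reached by 4 of 35 splits, with 3693 in the highest other, and the 2 genes of the stigmasterol interaction by 10 of 100, with 1457 in the highest other. Chance is not excluded for these 2 counts, and splits that call many more genes than the real one point to a structure of the samples that the groups do not describe. For BPA in WT the real count was 0, which every split reaches (35 of 35, with 638 genes in the highest other), so that test says nothing about chance. The 10 splits of 3 KO animals against 3 are too few for a share under 0.05: the real count was 3 for BPA, with 1 of 10 splits as large and 2 in the highest other, and 0 for stigmasterol, with 10 of 10 as large and 9 in the highest other.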
